A study of Mus musculus with 64 samples.

How the data were processed

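The libraries are labelled as mRNA sequencing of 6-month-old C57BL/6 mice, with RNA extracted with Qiagen RNeasy columns and libraries made with the TruSeq stranded kit. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 and the genome GRCm38 (mm10), without stating what each tool was used for. The deposited tables hold gene counts and FPKM, and per the notes the authors derived both from the same alignments, with no statement of annotation, strand setting or filter. Of 48795 genes in the count table, 48435 (99.3%) have an identifier in GENCODE M21, the reference used here, and 134 table lines repeat a gene symbol. The deposited FPKM equalled the count divided by gene length in kilobases and by the column total, in its usual scaling. Columns were matched to libraries by the column name given in each sample's description. The sum of the counts per library was used as the depth, and 0 columns of per-library values were left unused.

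The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept with filterByExpr at a minimum count of 10, scaled with TMM factors and tested with robust quasi-likelihood fits in edgeR. Within each tissue label the 32 libraries were fitted with 4 genotypes and the labelled sex, which left 27 residual degrees of freedom. The comparisons across tissue labels used all 64 libraries with 8 groups and sex within tissue (54 residual degrees of freedom). Sex by Q140 KI was fitted with 24 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Samples, the design, a set of alternatives and the naming rule were written before the data were examined, and what was added or changed later is named as such. Log values for scores used a prior count of 2, intervals are 95% confidence intervals, and SD is over 8 libraries.

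Genes were named by a rule. Mlh1 and Htt were named in every comparison. In the striatum-labelled comparisons of Q140 KI with wild type and of Q140 KI x Mlh1+/- with Q140 KI, the 10 largest increases and 10 largest decreases among called genes of a mean log2 CPM of at least 1 were to be named, and 5 and 5 elsewhere. From each list up to 4 members of the smallest p were open to naming. Genes without a common symbol were counted but not named.

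The remaining Mlh1 and Htt values are given here so that each comparison has both. Mlh1 was at 0.05 by the striatum and −0.03 by the cortex label in Q140 KI against wild type, at 0.00 by the cortex label in Q140 KI x Mlh1+/- against wild type and at −0.07 in Q140 KI x Mlh1+/- against Mlh1+/-. It was at 0.24 and −0.04 in the interactions, −0.17 in the sex interaction, −0.07 between the tissue labels in wild type and 0.08 in the tissue by Q140 KI interaction. The value of 0.24 was 0.16 without Q140 KI x Mlh1+/- female 1, and that of −0.17 was −0.087 without Q140 KI male 4. Htt was at 0.00 by the cortex label in Q140 KI against wild type, at 0.04 and 0.07 in Mlh1+/- against wild type, and at −0.01 and 0.05 in Q140 KI x Mlh1+/- against Q140 KI. It was at 0.01 and 0.06 in Q140 KI x Mlh1+/- against wild type, −0.03 and −0.02 against Mlh1+/-, −0.05 and −0.02 in the interactions, 0.08 in the sex interaction, −0.07 between the tissue labels and 0.02 in the tissue by Q140 KI interaction. None of these passed the threshold.

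Gene lists were written from general knowledge of cell types and pathways, 28 in all, and tested in 15 comparisons (420 tests) with camera at a preset correlation of 0.01, with a correlation estimated from the data, and with fry. Some genes stood on more than 1 list, such as 10 of the projection neuron identity genes, 5 direct-pathway and 4 indirect-pathway ones, so these lists are not independent. A list test with the preset correlation takes members as nearly independent, which co-varying cell type markers are not. The p values of the list tests were adjusted over the 28 lists within each comparison and not over all 420 tests. Members were also adjusted over the list alone.

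Each animal was labelled to have given 1 library per tissue, and the labels were the only pairing information. The values of the pairs were compared once. After removal of group means, the 2 libraries of an animal had a mean correlation of 0.018 (range −0.221 to 0.267, 9 of 32 above 0.1), and libraries of different animals one of −0.0007. Of 32 striatum-labelled libraries, 5 were closest to the cortex-labelled library of their own animal among the 8 of their genotype. The main test, fixed in advance, had no block for the animal, and the block was an alternative. The lowest chi-square per gene between libraries of a group was 9.84, with a median of 31.6 over 224 pairs and 14560 genes. It was 18.9 for the 2 libraries of an animal and 8.59 for the 1760 other pairs. Repeated sequencing of 1 library would lie near 1, so that no pair of the 64 was such a repeat. Separate preparations from the same RNA can lie higher and were not excluded. Cortex-labelled libraries sat in plate columns 1 to 4 and striatum-labelled ones in columns 5 to 8, which confounds plate column and tissue label. Under the striatum label plate column and genotype are partly confounded too. Column 6 held only Mlh1+/- and Q140 KI x Mlh1+/- libraries, and column 5 held no Mlh1+/- library.

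The method was tested on simulated data, with 50 genes changed per fold in counts drawn from the fitted spread. The changed genes were taken from the more highly expressed ones only, and each gene was drawn independently of the others. The rates therefore do not carry over to weakly expressed genes or to structure that libraries share, such as the Thy1 ranges. In the striatum-labelled comparison of Q140 KI with wild type edgeR recovered 48% of genes changed 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 7 false calls of 173. In the cortex-labelled one it recovered 72%, 96%, 100% and 100%, with 16 false calls of 200. In the wild-type tissue comparison it recovered 72%, 94%, 98% and 100%, with 8 false calls of 190.

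The score took the genes called between Q140 KI and wild type in 4 libraries of each group, or the 100 of smallest p where fewer than 20 were called, and applied them to the other 4, with the wild-type mean as 0. In the striatum label 0 genes were called in either set, so 100 were used in both. In the cortex label 0 and 92 were called. The slope and its alternatives were planned but not run, because 0 genes were called.

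Alternatives were DESeq2, limma on FPKM, RLE scaling, no filter, an adjusted p under 0.1, fits of 2 genotypes, a single sex, no sex term, plate column as a term, replicate number or animal as a block, and each library left out in turn. Alternatives added after the data were seen were 5 surrogate variables, a fit of the libraries whose sex-linked genes match the label, log Xist in place of the sex label, a fit without 2 libraries that stood apart, and the protocadherin list without each cortex-labelled library in turn. The wild-type tissue contrast was first coded at the male level, which called 410 genes, and was replaced, after that count was seen, by the mean of both sexes, which called 896. The minimums for Xist and Ddx3y, the comparison of marker genes with the tissue labels and the Thy1 ranges were chosen after the values were seen.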

Results

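RNA was sequenced from brain tissue of 6-month-old C57BL/6 mice labelled as wild type, Mlh1+/-, heterozygous Q140 KI or heterozygous Q140 KI x Mlh1+/-, the last 2 called Q140 KI and Q140 KI x Mlh1+/- here. Q140 KI mice carry a knock-in allele of Htt, the huntingtin gene, with an expanded CAG repeat. Mlh1 encodes a DNA mismatch repair protein that takes part in the expansion of such repeats, and Mlh1+/- mice lack 1 functional copy. The design therefore addresses whether the loss of 1 Mlh1 copy alters the transcriptome of Q140 KI mice, in striatum and in cortex. The labels describe 32 animals that each gave a striatal and a cortical library, so that 64 libraries fall into 8 groups of 8. Each group holds 4 females and 4 males by label, apart from the Q140 KI groups, which hold 3 females and 5 males. The total count per library ranged from 32913267 to 57569077, with a median of 39609305. Expression levels are deposited gene counts scaled by depth and TMM factors (CPM).

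Mlh1, the gene that the labels describe as lost from 1 chromosome, was 0.08 log2 units lower in Mlh1+/- than in wild-type libraries by the striatum label and 0.07 higher by the cortex label, and neither passed its test. It is ENSMUSG00000032498 and lies on the minus strand of chromosome 9 from 111228228 to 111271791 in GRCm38. Among striatum-labelled libraries its level was 7.75 ± 0.80 CPM in wild type, 7.29 ± 0.98 in Mlh1+/-, 7.91 ± 0.97 in Q140 KI and 8.95 ± 2.42 in Q140 KI x Mlh1+/- (SD, n = 8 each). Among cortex-labelled libraries it was 8.15 ± 0.72, 8.56 ± 0.72, 7.97 ± 0.67 and 8.17 ± 0.41 CPM in the same order (SD, n = 8 each). The log2 fold change of Mlh1+/- against wild type was −0.08 (95% confidence interval −0.32 to 0.15) by the striatum label and 0.07 (−0.06 to 0.21) by the cortex label. The log2 fold change of Q140 KI x Mlh1+/- against Q140 KI was 0.16 (−0.08 to 0.40) by the striatum label and 0.03 (−0.10 to 0.17) by the cortex label. Of the striatum-labelled Q140 KI x Mlh1+/- libraries, female 1 and female 3 were at 13.4 and 12.1 CPM of Mlh1 and the other 6 at 7.05 to 8.54. The value of 0.16 was 0.07 without female 1, −0.14 in males by label and −0.04 without both females, a choice made after the values were seen. A log2 fold change of −1, which a transcript level proportional to gene dosage would give, lay outside these 4 intervals. The labels do not describe the Mlh1 allele, and an allele that still made a transcript would also leave the count unchanged. Htt (ENSMUSG00000029104, plus strand of chromosome 5 from 34761740 to 34912534) was at 207 ± 13.6 CPM in wild-type and 210 ± 16.1 CPM in Q140 KI striatum-labelled libraries (SD, n = 8 each), a log2 fold change of 0.02 (−0.10 to 0.14).

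**Figure D1:**
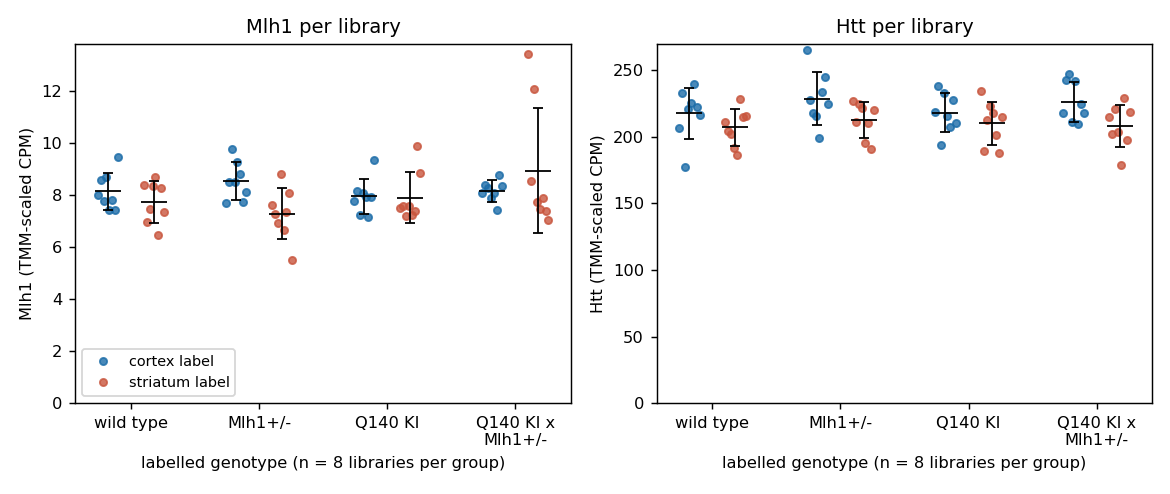
Mlh1 (left) and Htt (right) in TMM-scaled CPM (vertical axes) by labelled genotype (horizontal axes), with 1 point per library, blue for the cortex label and red for the striatum label. Bars give the mean and SD of 8 libraries. Mlh1 in the libraries labelled Mlh1+/- overlaps that in the wild-type libraries under both tissue labels.

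The transcripts of sex chromosomes did not follow the sex labels. Xist, the X-inactivation RNA made in females, and Ddx3y, a Y-linked helicase gene, were mutually exclusive in 63 of 64 libraries, at minimums of 20 CPM for Xist and 2 CPM for Ddx3y that were set after the values had been seen. The sex shown by these genes matched the label in 15 of 32 striatum-labelled and 14 of 32 cortex-labelled libraries (29 of 64 in all). Over the 63 libraries with exactly 1 of these transcripts, label and transcript were not associated (two-sided Fisher's exact test, p = 0.616). The 2 libraries labelled as the same animal showed the same sex in 14 of 32 animals (two-sided Fisher's exact test over 31 animals, p = 0.724). The remaining library, female F1 of the cortex-labelled Mlh1+/- group, held 0.05 CPM of Xist and 0 of Ddx3y.

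**Figure D2:**
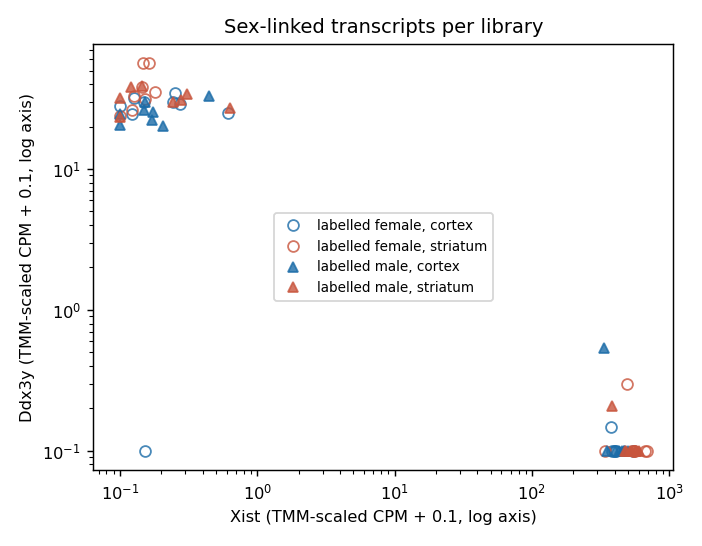
Xist (horizontal log axis) against Ddx3y (vertical log axis) in TMM-scaled CPM with 0.1 added, 1 point per library. Open circles are libraries labelled female, filled triangles libraries labelled male, blue the cortex label and red the striatum label. Both labels occur in both clouds, and 1 library lacks both transcripts.

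The tissue labels were not matched by marker genes of either tissue. Slc17a7, the vesicular glutamate transporter of cortical projection neurons, had a median of 1802 CPM in striatum-labelled and 1842 CPM in cortex-labelled libraries. Tbr1, a transcription factor of cortical excitatory neurons, had medians of 203 and 193 CPM, and Satb2, another such factor, of 111 and 97.5 CPM. Genes of striatal projection neurons had lower medians under the striatum label. Ppp1r1b (DARPP-32) had 87.1 CPM under the striatum label and 131 CPM under the cortex label, Pde10a 65.9 and 91.8 CPM, Penk 45.1 and 73.4 CPM, and Drd2, the dopamine D2 receptor, 1.24 and 4.80 CPM. In 0 of 64 libraries did the Ppp1r1b level exceed that of Slc17a7, and the lowest ratio of Slc17a7 to Ppp1r1b was 7.25. Because the sex-linked genes and the tissue markers went against the labels, groups are called by their labels throughout, and every direction given is one between labelled groups. The genotype labels rest on the same match of columns to libraries, and no value here verified them. Each comparison is therefore one of labelled genotypes and not a measured effect of an allele.

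**Figure D3:**
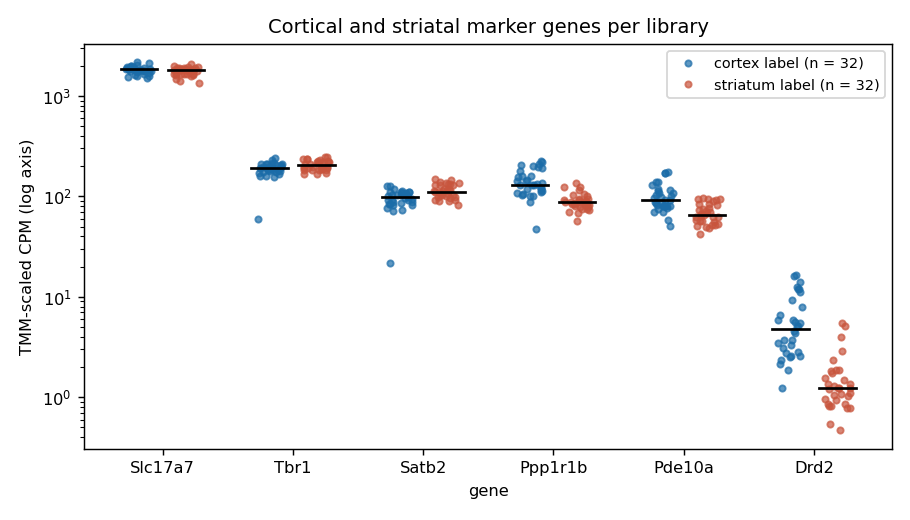
Marker genes of cortical excitatory neurons (Slc17a7, Tbr1, Satb2) and of striatal projection neurons (Ppp1r1b, Pde10a, Drd2) in TMM-scaled CPM (vertical log axis), 1 point per library. Blue is the cortex label and red the striatum label, with 32 libraries each, and bars are medians. The cortical markers are at like levels under both labels, and the striatal markers have lower medians under the striatum label.

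Thy1, a surface glycoprotein of neurons, separated the libraries within groups rather than between them. It lay between 1585 and 3171 CPM in 31 libraries and between 590.5 and 902.1 CPM in the other 33. Each of the 8 groups held libraries of both kinds. The number of libraries in the upper range was 6 of 8 in wild type, 2 in Mlh1+/-, 3 in Q140 KI and 5 in Q140 KI x Mlh1+/- by the striatum label. By the cortex label it was 3, 5, 6 and 1 in the same order.

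**Figure D4:**
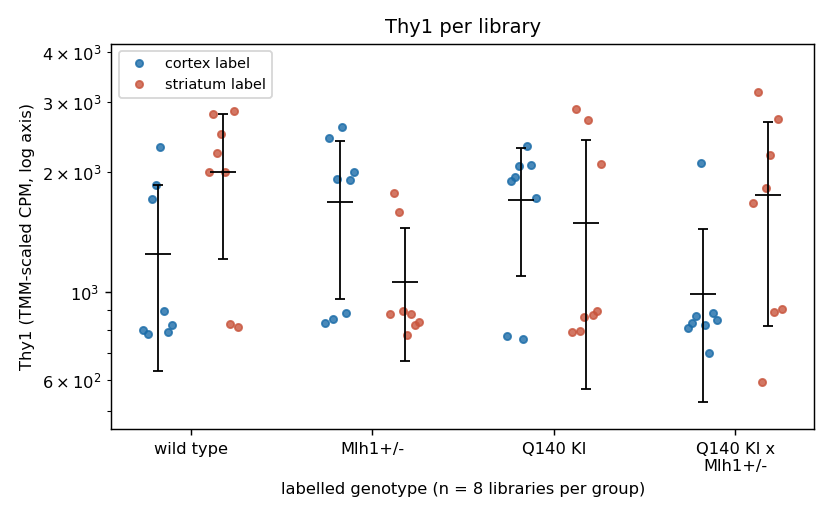
Thy1 in TMM-scaled CPM (vertical log axis) by labelled genotype (horizontal axis), 1 point per library, blue for the cortex label and red for the striatum label. Bars give the mean and SD of 8 libraries. The libraries of each group fall on both sides of a gap between 902.1 and 1585 CPM.

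The comparison of Q140 KI with wild type asks for the effect of the knock-in in mice with both Mlh1 copies. Under the striatum label, 2 endothelial genes were higher in Q140 KI when adjusted over the list alone, out of 13 measured endothelial and mural markers, and 0 over all genes. Cldn5, a tight-junction protein of brain endothelium, was at 24.6 ± 4.49 CPM against 18.1 ± 3.60 CPM in wild type (SD, n = 8 each), a log2 fold change of 0.44 (0.16 to 0.72). Itm2a, a membrane protein enriched in brain vessels, had a log2 fold change of 0.32 (0.12 to 0.53), and for both genes 8 of 8 Q140 KI libraries lay above the wild-type median. The endothelial list as a whole lay higher than other genes (camera with a preset correlation, adjusted p = 7.12e-06), with adjusted p = 0.807 with an estimated correlation. Markers of striatal projection neurons, whose loss of expression is the usual mark of Huntington's disease models, went both ways, with 21 of 38 positive. They had a median log2 fold change of 0.01, a mean of −0.01 and an adjusted camera p of 0.796 for a higher list. The striatum-labelled libraries had no striatal profile, with a median of 87.1 CPM for Ppp1r1b and 1802 CPM for Slc17a7. This result therefore does not bear on a loss of expression in striatal neurons. The 21 measured protocadherin beta genes, which encode neuronal adhesion proteins, had a median of 0.03, with an adjusted p of 0.492 in limma's camera. The 15 measured microglia markers were each negative, with a median of −0.39 (adjusted camera p = 3.45e-06, adjusted p = 0.835 with an estimated correlation). With log2 Thy1 CPM as a covariate their median was −0.0557, and 3 of 8 Q140 KI libraries against 6 of 8 wild-type ones were in the upper Thy1 range. Ctss, a lysosomal protease of microglia, was at −0.53 (−1.36 to 0.30), and at −0.90 without Q140 KI female 2. Immediate early genes, which neuronal activity induces, had a median of 0.40 over 16 members (adjusted camera p = 0.0227, adjusted p = 0.835 with an estimated correlation), and Btg2 was at 0.71 (0.04 to 1.39) with 5 of 8 libraries above the wild-type median, and at 0.47 without Q140 KI male 5. The 21 cholesterol synthesis genes were each negative, with a median of −0.07 (adjusted camera p = 0.000164, adjusted p = 0.835 with an estimated correlation). Over all 18472 genes tested, edgeR called 0, with 541 at an unadjusted p under 0.05 where 924 would be expected of independent genes. Other labellings of the same libraries gave a median of 863 and up to 2298. DESeq2 called 1 gene, Gpr12, named here after its values were seen (edgeR log2 fold change 0.35, adjusted p = 0.406), and limma on FPKM called 0.

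The comparison of Mlh1+/- with wild type asks for the effect of losing 1 Mlh1 copy alone. Under the striatum label, microglial and interferon genes were lower in the Mlh1+/- libraries when adjusted over each list alone. Of 15 measured microglia markers 13 were lower by that adjustment (0 over all genes), with a median of −1.06 (adjusted camera p = 5.67e-16, adjusted p = 0.180 with an estimated correlation). Trem2, a lipid receptor of microglia, was at 14.3 ± 2.18 CPM against 51.1 ± 27.0 CPM in wild type (SD, n = 8 each), a log2 fold change of −1.80 (−3.05 to −0.55). C1qa, a complement component, was at −1.23 (−2.07 to −0.38) and Ctss at −1.27 (−2.11 to −0.43), and for each of these 3 genes 8 of 8 Mlh1+/- libraries lay below the wild-type median. Of 15 interferon response genes 11 were lower adjusted over the list alone (0 over all genes), with a median of −0.73 (adjusted camera p = 5.11e-15, adjusted p = 0.180 with an estimated correlation), among them the interferon regulatory factors Irf7 at −1.28 (−2.04 to −0.52) and Irf9 at −0.61 (−0.96 to −0.25). Prkcd, a protein kinase gene of thalamic neurons, was at −0.47 (−0.79 to −0.15) and lower adjusted over its list of 8 alone. Plate column 6 held Mlh1+/- but no wild-type libraries of this label, so genotype and plate column are partly confounded here. Thy1 was at 1055 ± 388 CPM in these Mlh1+/- libraries and at 2002 ± 795 CPM in the wild-type ones (SD, n = 8 each), with 2 and 6 of 8 in the upper range. With log2 Thy1 CPM as a covariate the microglia median was −0.16, and with 5 surrogate variables Trem2 was at −0.05, C1qa at −0.12, Ctss at −0.15, Irf7 at −0.43 and Irf9 at −0.23.

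Some interneuron, direct-pathway and choroid plexus markers lay higher in the same striatum-labelled Mlh1+/- libraries. Adjusted over each list alone, 5 of 11 interneuron markers, 3 of 8 direct-pathway projection neuron markers and 2 of 9 choroid plexus markers were higher, and 0 over all genes. Drd1, the dopamine D1 receptor, was at 0.41 (0.11 to 0.71) and Tac1, the substance P precursor, at 0.55 (0.24 to 0.87). The cholinergic genes Chat and Slc5a7 were at 1.75 (0.64 to 2.85) and 1.77 (0.76 to 2.79) on means under 3 CPM, and 4 and 3 of 8 libraries lay above the wild-type median. Chat was at 0.84 without Mlh1+/- female 3 and Slc5a7 at 1.08 without Mlh1+/- male 3. Ttr, the transthyretin gene of the choroid plexus, was at 6.03 (2.20 to 9.86), with a mean of 275 ± 562 CPM against 4.38 ± 5.32 CPM (SD, n = 8 each), and at 3.65 without Mlh1+/- female 3. The adjusted camera p was 0.00121 for interneuron, 0.0214 for direct-pathway and 0.00279 for choroid plexus markers. With an estimated correlation these became adjusted p = 0.180, adjusted p = 0.180 and adjusted p = 0.507. Over all 18472 genes edgeR called 0, with 1220 at an unadjusted p under 0.05. DESeq2 called 3 (Abca9, Ifi27l2a and Gm8281, named after their values were seen) and limma on FPKM 0. A fit of only these 16 libraries, whose spread is not shared with the other genotypes, called 252 genes, 7 higher and 245 lower, with Trem2 at adjusted p = 0.0271.

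The comparison of Q140 KI x Mlh1+/- with Q140 KI is the central one for the effect of Mlh1 dosage on the knock-in. Under the striatum label, immediate early genes were lower in Q140 KI x Mlh1+/-, with 9 of 16 past the threshold adjusted over the list alone and 0 over all genes. The transcription factor gene Junb was at 76.9 ± 38.9 CPM against 157 ± 66.3 CPM in Q140 KI (SD, n = 8 each), a log2 fold change of −1.08 (−1.68 to −0.49), with 7 of 8 libraries below the Q140 KI median. Ier2 was at −0.95 (−1.49 to −0.42), Btg2 at −1.09 (−1.78 to −0.40) and the phosphatase gene Dusp1 at −0.87 (−1.46 to −0.28). The median of the list was −0.79 (adjusted camera p = 9.11e-13, adjusted p = 0.676 with an estimated correlation). Of 9 choroid plexus markers 4 were higher adjusted over the list alone, with an adjusted camera p of 0.256. Ttr among them was at 5.26 (1.28 to 9.23), with 2 of 8 libraries above the Q140 KI median, and without the Q140 KI x Mlh1+/- library of male 1 it was −1.03. It was −1.22 in females by label and −1.33 in libraries whose sex-linked genes match the label. Pcdhga9, a gamma protocadherin, was lower adjusted over its list alone (−0.36, −0.55 to −0.17), while the 31 alpha and gamma members had a median of 0.00, a mean of −0.03 and an adjusted camera p of 0.271 for a lower list. Projection neuron markers had 15 of 38 positive, with a median of −0.04 and an adjusted p of 0.296 in limma's camera, again in libraries without a striatal profile. Mismatch repair genes had 12 of 23 positive, with a median of 0.00, a mean of 0.03 and an adjusted camera p of 0.981. Microglia markers had a median of 0.48 (adjusted camera p = 0.0484, adjusted p = 0.864 with an estimated correlation), and of 0.132 with log2 Thy1 CPM as a covariate, with 5 against 3 of 8 libraries in the upper Thy1 range. Plate column 6 held Q140 KI x Mlh1+/- but no Q140 KI libraries of this label, so these groups also differ in plate column. Over all 18472 genes edgeR called 0, with 942 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each.

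A per-library score of the Q140 KI profile, in which no library was scored on genes chosen with it, was compared between the same groups. By the striatum label it was 0.10 ± 0.59 in Q140 KI x Mlh1+/- and −0.26 ± 0.54 in Q140 KI, a difference of 0.36 log2 units (two-sided exact permutation test over 12870 arrangements, n = 8 each, p = 0.220). A profile that carried over between libraries would give Q140 KI a positive score. Its difference from wild type was −0.26 (exact permutation p = 0.310). With the sets of 4 split by first and last numbers in place of odd and even ones these 2 differences were 0.04 (exact permutation p = 0.784) and 0.03 (exact permutation p = 0.836). By the cortex label the score was −0.24 ± 0.24 in Q140 KI x Mlh1+/- and −0.38 ± 0.29 in Q140 KI, a difference of 0.15 (exact permutation p = 0.285), and the difference of Q140 KI from wild type was −0.38 (exact permutation p = 0.0151). That last difference was 0.06 (exact permutation p = 0.690) with the split by first and last numbers. Each set of 4 was scored on its own genes, but the permutations of the score did not keep the sets apart. Libraries of a set are therefore not independent, and no conclusion rests on these p values. The planned slope of the knock-in effect in Mlh1+/- on that in mice with both copies could not be computed, since edgeR called 0 genes in either comparison.

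Against wild type, the striatum-labelled Q140 KI x Mlh1+/- libraries had 1 lower heat shock gene and 2 higher endothelial genes, adjusted over each list alone. Hspa1b, an inducible heat shock protein 70 gene, was at −0.60 (−0.94 to −0.26) with 8 of 8 libraries below the wild-type median, and the 14 chaperone genes had a median of −0.16 (adjusted camera p = 0.000140, adjusted p = 0.852 with an estimated correlation). Slco1a4, an endothelial transporter gene, was at 0.43 (0.16 to 0.71) and Itm2a at 0.29 (0.09 to 0.50). The 13 endothelial markers had a median of 0.15 (adjusted camera p = 0.00103, adjusted p = 0.852 with an estimated correlation). Immediate early genes were each negative, with a median of −0.40 (adjusted camera p = 2.31e-06, adjusted p = 0.852 with an estimated correlation). Mlh1 was at 0.21 (−0.03 to 0.44), and at −0.0076 without the 2 females of high Mlh1. Over all genes edgeR called 0 with 1186 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each.

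The comparison with Mlh1+/- is, by label, that of the knock-in in mice with 1 Mlh1 copy. Striatum-labelled Q140 KI x Mlh1+/- libraries had higher levels of most microglia markers there. Levels of some striatal neuron and interneuron markers were lower. Adjusted over each list alone, 14 of 15 microglia markers and 11 of 15 interferon genes were higher, and 8 of 11 interneuron, 5 of 38 projection neuron and 5 of 7 indirect-pathway markers were lower, with 0 over all genes. Trem2 was at 1.97 (0.72 to 3.22), its signalling adaptor gene Tyrobp at 1.92 (0.66 to 3.18) and the interferon-induced GTPase gene Gbp3 at 0.91 (0.37 to 1.45). Trem2 lay above the Mlh1+/- median in 5 of 8 libraries, and with 5 surrogate variables in the fit Trem2 was at −0.18 and Tyrobp at −0.24. Chat was at −2.28 (−3.43 to −1.14), Tac1 at −0.55 (−0.87 to −0.24), Drd1 at −0.51 (−0.81 to −0.21) and Drd2 at −0.92 (−1.72 to −0.12). Chat was at −1.38 without Mlh1+/- female 3, and Drd2 at −0.51 without Mlh1+/- male 3. The medians were 1.18 for microglia, 0.64 for interferon and −0.43 for interneuron markers, with adjusted camera p values of 2.10e-07, 6.57e-08 and 0.000150. With an estimated correlation these became adjusted p = 0.433, adjusted p = 0.368 and adjusted p = 0.217. Thy1 was at 1746 ± 925 CPM here and 1055 ± 388 CPM in Mlh1+/- (SD, n = 8 each), and with it as a covariate the microglia median was 0.242. The same Mlh1+/- libraries entered the comparison with wild type, so the opposite signs there are not independent. Mlh1 itself was at 0.29 (0.05 to 0.53) in this comparison of striatum-labelled libraries, with an adjusted p of 0.336 in edgeR. It was 0.20 without female 1 and 0.08 without females 1 and 3 of Q140 KI x Mlh1+/-. In edgeR 0 genes passed over all genes, with 2131 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each.

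The interaction asks whether both alleles together depart from the sum of their separate effects. Under the striatum label, 15 of 15 microglia markers and 9 of 15 interferon genes had a positive interaction past the threshold adjusted over each list alone, and 4 of 16 immediate early genes and 3 of 8 direct-pathway markers a negative one. Ctss was at 1.81 (0.63 to 2.99), Irf9 at 0.80 (0.30 to 1.30), Btg2 at −1.63 (−2.58 to −0.67) and Tac1 at −0.69 (−1.13 to −0.24). With log2 Thy1 CPM, which was unevenly spread over these groups, as a covariate the microglia median was 0.289 in place of 1.58. With 5 surrogate variables Ctss was at 0.24, Irf9 at 0.27 and Trem2 at −0.05. The medians were 1.58 for microglia, 0.80 for interferon and −0.89 for immediate early genes, with adjusted camera p values of 5.90e-11, 1.74e-09 and 3.01e-07. With an estimated correlation these became adjusted p = 0.386, adjusted p = 0.386 and adjusted p = 0.522. Over all genes edgeR called 0 with 1662 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each. The sex by Q140 KI interaction by label, on 3 to 5 libraries per sex and genotype, had 1 indirect-pathway gene past the threshold adjusted over the list alone, Gpr6, an orphan receptor gene, at −1.18 (−1.87 to −0.49). Its 7-member list had a median of −0.44 (adjusted camera p = 0.0221, adjusted p = 0.607 with an estimated correlation). The test over all genes called 0 in edgeR, with 492 at an unadjusted p under 0.05, and DESeq2 called the Y-linked genes Uty, Ddx3y and Eif2s3y, named after their values were seen. The sex-linked genes matched the label in 6 of the 8 Q140 KI and 4 of the 8 wild-type libraries of this contrast.

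Under the cortex label, Q140 KI against wild type had 3 of 10 oligodendrocyte precursor markers past the threshold adjusted over the list alone, in both directions. Olig1, a transcription factor gene of the oligodendrocyte lineage, was at 0.15 (0.04 to 0.27), Cspg4, the NG2 proteoglycan gene, at 0.17 (0.04 to 0.31) and Lhfpl3 at −0.29 (−0.52 to −0.07). The list had an adjusted camera p of 0.306. Immediate early genes were each negative, with a median of −0.30 (adjusted camera p = 0.000102, adjusted p = 0.797 with an estimated correlation). Chaperone genes had 13 of 14 negative and a median of −0.14 (adjusted camera p = 0.00180, adjusted p = 0.797 with an estimated correlation), and 15 of 15 astrocyte markers were positive with a median of 0.07 (adjusted camera p = 0.00321, adjusted p = 0.797 with an estimated correlation). Projection neuron markers had 18 of 38 positive, with a median of −0.00 and an adjusted camera p of 0.933. Over all 18487 genes edgeR called 0 with 620 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each.

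The alpha and gamma protocadherin genes, which encode cell surface proteins of neurons, lay higher in cortex-labelled Mlh1+/- than in wild-type libraries. Of 31 measured alpha and gamma members 29 were positive, with a median of 0.15, and 2 were past the threshold adjusted over the list alone (0 over all genes). Pcdhgb2 was at 10.2 ± 1.99 CPM against 7.70 ± 0.96 CPM (SD, n = 8 each), a log2 fold change of 0.40 (0.18 to 0.62) with 8 of 8 libraries above the wild-type median, and Pcdhga5 was at 0.25 (0.09 to 0.41). This list passed with a preset correlation (adjusted camera p = 9.01e-08) and with an estimated one (adjusted p = 0.0292 with an estimated correlation). Both values were adjusted over the 28 lists of this comparison and not over the 420 tests. In fits without 1 library, run after this was seen, it held in 27 of 32, with adjusted p from 0.0109 to 0.0675 with an estimated correlation. It did not hold without female 2, male 2 or male 4 of Mlh1+/-, or male 1 or male 2 of wild type. All of these are among the libraries compared. The 32 also include libraries of the other genotypes, which enter this comparison only through the shared fit. Without Mlh1+/- female 1, the library that lacks Xist and Ddx3y, adjusted p = 0.0423 with an estimated correlation, 0 members passed adjusted over the list alone and Pcdhgb2 was at 0.31. Rpl3, a ribosomal protein gene, was under 4 CPM in 0 of 8 of these Mlh1+/- and 5 of 8 of these wild-type libraries, and at 17.9 CPM or more in the others. With log2 Rpl3 CPM as a covariate, chosen after these values were seen, the median of the list was 0.11 and 1 member passed adjusted over the list alone (adjusted camera p = 0.000297, adjusted p = 0.284 with an estimated correlation). With log2 Thy1 CPM in its place the median was 0.16 (adjusted p = 0.0291 with an estimated correlation). The 21 beta members had 11 positive, with a median of 0.02 (adjusted p = 0.687 in limma's camera). Alpha members share exons with each other, and so do gamma members, so reads could be split or lost among them in the authors' counting. Projection neuron markers had 32 of 38 negative, with a median of −0.17 (adjusted camera p = 1.65e-06, adjusted p = 0.702 with an estimated correlation), and microglia markers had 14 of 15 positive, with a median of 0.23 (adjusted camera p = 0.0123, adjusted p = 0.741 with an estimated correlation). Of 10 oligodendrocyte precursor markers, Cspg4 at 0.19 (0.06 to 0.33) and Olig1 at 0.16 (0.05 to 0.28) were higher and Lhfpl3 at −0.30 (−0.53 to −0.08) lower adjusted over the list alone. The same wild-type libraries served the comparison with Q140 KI, where these genes had the same signs. Thy1 was at 1678 ± 721 CPM in these Mlh1+/- and 1245 ± 614 CPM in these wild-type libraries (SD, n = 8 each). Over all genes edgeR called 0 with 1321 at an unadjusted p under 0.05, and limma on FPKM called 0. DESeq2 called Rps4l, a ribosomal protein gene named after its values were seen, which in edgeR had a log2 fold change of 0.72 and an adjusted p of 0.289 and was called without wild-type library F1 or M1.

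Under the cortex label, potassium channel genes were higher and cholesterol synthesis genes lower in Q140 KI x Mlh1+/- than in Q140 KI, each for a few members adjusted over the list alone. Kcnq5, Kcna1 and Kcnq3, subunits of neuronal potassium channels, were at 0.19 (0.07 to 0.30), 0.23 (0.09 to 0.36) and 0.21 (0.06 to 0.36), and 3 of 17 members passed. The channel list had a median of 0.10 (adjusted camera p = 0.00332, adjusted p = 0.0856 with an estimated correlation). The sterol enzyme genes Msmo1 and Dhcr7 were at −0.20 (−0.32 to −0.08) and −0.18 (−0.29 to −0.07), with 8 of 8 libraries below the Q140 KI median for both, and 20 of 21 members were negative with a median of −0.11 (adjusted camera p = 3.84e-06, adjusted p = 0.882 with an estimated correlation). Of these libraries 1 of 8 Q140 KI x Mlh1+/- and 6 of 8 Q140 KI ones were in the upper Thy1 range, and 3 of 8 and 7 of 8 had Rpl3 under 4 CPM. With log2 Thy1 CPM as a covariate, chosen after its ranges were seen, the cholesterol list had a median of −0.02 and 11 of 21 negative, with an adjusted p of 0.752 in limma's camera, the channel list had a median of 0.09, and 0 members of either passed adjusted over the list alone. The channel list then passed camera neither with a preset correlation nor with an estimated one (adjusted p = 0.5 with an estimated correlation). With log2 Rpl3 CPM as the covariate the medians were −0.16 (adjusted camera p = 1.10e-11, 6 members past the threshold adjusted over the list alone) and 0.115 (adjusted camera p = 0.00836, 1 member), with adjusted p = 0.345 and adjusted p = 0.175 with an estimated correlation. That fit called 6 genes over all genes, where the fits without a covariate and with Thy1 called 0. Pcolce2, which encodes an enhancer of procollagen processing, was at 4.18 ± 0.76 CPM against 2.80 ± 0.36 CPM in Q140 KI (SD, n = 8 each), with 8 of 8 libraries above the Q140 KI median. Its log2 fold change of 0.58 had an adjusted p of 0.0648 in edgeR, and it was named after its values were seen. It passed in DESeq2 (adjusted p = 0.00132) and when any of 4 single libraries was left out, namely male 3 of Mlh1+/-, female 2 of Q140 KI x Mlh1+/-, or female 1 or male 3 of Q140 KI. Ttr was at 4.12 (1.65 to 6.59) with 4 of 8 libraries above the Q140 KI median, at 2.40 without Q140 KI x Mlh1+/- male 4 and at −1.28 in libraries whose sex-linked genes match the label. Tested over all genes, 0 passed in edgeR, with 1121 at an unadjusted p under 0.05, DESeq2 called 2 (Pcolce2 and Gm3608), and limma on FPKM called 0.

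The remaining cortex-labelled comparisons again involved immediate early, cholesterol synthesis and oligodendrocyte precursor genes. Against wild type, Q140 KI x Mlh1+/- had 0 of 28 lists with a member past the threshold adjusted over the list alone. Immediate early genes there had a median of −0.26 (adjusted camera p = 1.51e-05, adjusted p = 0.663 with an estimated correlation). Over all genes edgeR called 0 with 435 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each. Against Mlh1+/-, 2 of 21 cholesterol synthesis genes were lower and 2 of 9 choroid plexus markers higher adjusted over the list alone. Dhcr7 and Msmo1 were both at −0.18, and Aqp1, a water channel gene, was at 1.51 (0.44 to 2.58). The cholesterol list had a median of −0.15 (adjusted camera p = 3.82e-07, adjusted p = 0.472 with an estimated correlation), and microglia markers had 15 of 15 negative and a median of −0.39 (adjusted camera p = 3.18e-05, adjusted p = 0.472 with an estimated correlation). Thy1 was at 984 ± 457 CPM in these Q140 KI x Mlh1+/- libraries (SD, n = 8), with 1 of 8 in the upper range against 5 of 8 for Mlh1+/-, and Rpl3 was under 4 CPM in 3 of 8 against 0 of 8. With every gene tested, edgeR called 0, with 1327 at an unadjusted p under 0.05, and DESeq2 and limma on FPKM called 0 each. In the interaction by the cortex label, Msmo1 was at −0.30 (−0.47 to −0.13), Lhfpl3 at 0.55 (0.23 to 0.87), Olig1 at −0.24 (−0.40 to −0.08) and Cspg4 at −0.28 (−0.47 to −0.08), each past the threshold adjusted over its list alone. The upper Thy1 range held 3 of 8 wild-type, 5 of 8 Mlh1+/-, 6 of 8 Q140 KI and 1 of 8 Q140 KI x Mlh1+/- libraries of these groups. Rpl3 was under 4 CPM in 5, 0, 7 and 3 of 8 in the same order. The alpha and gamma protocadherins had 27 of 31 negative, with a median of −0.14 (adjusted camera p = 0.00109, adjusted p = 0.295 with an estimated correlation). Over all genes edgeR called 0 with 1689 at an unadjusted p under 0.05, limma on FPKM called 0, and DESeq2 called 3 (Nr1d2, Kcnip4 and Fau, named after their values were seen). Nr1d2, a circadian repressor gene, was also called by edgeR without wild-type library M1, and had a log2 fold change of 0.54 with an adjusted p of 0.302 in the full fit.

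The wild-type libraries of both tissue labels were compared as a check of the tissue labels. Of 15 microglia markers 10 were higher under the striatum label, and of 38 markers of striatal projection neurons 18 were lower, which is the reverse of the labels for the latter. The upper Thy1 range held 6 of 8 of these striatum-labelled and 3 of 8 of these cortex-labelled libraries. The differences between the tissue labels given here, those of microglial genes included, were not separated from that spread of Thy1. The rankings that follow are among called genes with a common symbol and a mean log2 CPM of at least 1. The largest increases were in Clec7a at 3.88 (1.62 to 6.15) and Itgax at 3.84 (1.63 to 6.06), surface receptors of activated microglia, Lyz2, the lysozyme of myeloid cells, at 2.37 (1.30 to 3.43), the leukocyte antigen gene Cd52 at 2.33 (1.21 to 3.44) and the complement gene C4b at 2.21 (1.18 to 3.24). The largest decreases were in Drd2 at −2.29 (−3.23 to −1.34), Adora2a, the adenosine receptor gene of the same neurons, at −2.13 (−3.11 to −1.15), Pappa2 at −2.05 (−2.83 to −1.26), Baiap3 at −1.70 (−2.70 to −0.71) and Tacr1, the substance P receptor, at −1.47 (−2.09 to −0.85). Drd2 was at 1.62 ± 1.73 CPM under the striatum and 7.31 ± 4.76 CPM under the cortex label, and Clec7a at 10.3 ± 6.85 and 0.66 ± 0.88 CPM (SD, n = 8 each). Each of these 5 lower genes lay below the cortex-label median in 8 of 8 libraries, and Clec7a lay above it in 7 of 8. Altogether edgeR called 896 of 19170 genes, 512 higher and 384 lower, and DESeq2 1200. The contrast as first coded, at the male level, called 410 (182 higher, 228 lower), and Clec7a, Itgax, Lyz2, Cd52 and Baiap3 lost their calls there. Without a filter 548 genes were called, and Clec7a, Itgax and Baiap3 lost their calls.

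The projection neuron list had 18 of 38 lower over all genes and 23 adjusted over the list alone, with a median of −0.44. Rasd2 was at −0.56 (−0.78 to −0.34) and Gnal, an olfactory-type G protein gene of these neurons, at −0.46 (−0.64 to −0.28). The adjusted camera p of this list was 1.14e-13 (adjusted p = 0.163 with an estimated correlation). The factor Isl1, of the direct-pathway list only, was at −5.75 (−8.20 to −3.31) on a cortex-label mean of 1.13 CPM. The direct-pathway list had 4 of 9 lower over all genes (5 adjusted over the list alone) and the indirect-pathway list 4 of 7 (4), with adjusted p = 0.163 and adjusted p = 0.166 with an estimated correlation. The microglia list had 10 of 15 higher over all genes and 14 adjusted over the list alone, with a median of 1.08 (adjusted camera p = 1.81e-12, adjusted p = 0.166 with an estimated correlation), among them Ctss at 1.56 (0.90 to 2.22) and C1qa at 1.37 (0.72 to 2.02). Of 13 endothelial and mural markers 7 were lower over all genes and 9 adjusted over the list alone, with a median of −0.40 (adjusted camera p = 1.07e-07, adjusted p = 0.166 with an estimated correlation), among them Itm2a at −0.60 (−0.81 to −0.39) and Cldn5 at −0.65 (−0.97 to −0.33). Interferon genes had 2 of 15 higher over all genes and 6 adjusted over the list alone (adjusted camera p = 1.09e-05, adjusted p = 0.414 with an estimated correlation), with Bst2, an interferon-induced membrane protein gene, at 1.22 (0.54 to 1.91). Astrocyte markers had 1 of 15 higher over all genes, Gfap at 2.14 (1.12 to 3.16), and 5 adjusted over the list alone (adjusted camera p = 0.00133, adjusted p = 0.417 with an estimated correlation). Blood markers had 0 of 5 over all genes and 5 adjusted over the list alone (adjusted camera p = 1.65e-06, adjusted p = 0.163 with an estimated correlation). Hba-a1, an alpha globin gene with a near-identical copy, was at 2.31 (0.73 to 3.90). With the animal as a block Hba-a1 passed over all genes (adjusted p = 0.0499) and Baiap3 did not (adjusted p = 0.0538). Thy1 was at 2002 ± 795 CPM under the striatum and 1245 ± 614 CPM under the cortex label (SD, n = 8 each). The striatum-labelled males 2 and 4, in the lower Thy1 range, had Trem2 at 11.7 and 10.6 CPM. The 6 striatum-labelled libraries in the upper range had more Trem2 than each of the 3 cortex-labelled ones in that range. No value with Thy1 as a covariate is given for this comparison, so tissue label and Thy1 were not separated. The tissue label is confounded with the plate columns of the wells, so that plate column and tissue label cannot be told apart. The count was 530 without cortex-labelled female 2, 579 without striatum-labelled female 2 and 530 without striatum-labelled male 1. The calls of Clec7a, Itgax, Baiap3 and Bst2 were lost in 8, 7, 8 and 6 of the 16 fits that left out 1 library.

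The wild-type tissue comparison also gave values for the other lists. Over all genes, and in parentheses adjusted over the list alone, the number of higher members was 1 (3) of 15 cortical excitatory neuron markers, 3 (4) of 21 protocadherin beta genes, 2 (2) of 31 alpha and gamma protocadherins, 1 (2) of 21 cholesterol synthesis genes, 2 (2) of 23 mismatch repair genes, 1 (1) of 10 oligodendrocyte precursor markers and 0 (3) of 12 mitochondrially encoded genes. Pcdhb2 was at 0.85 (0.53 to 1.18) and Fdft1, squalene synthase, at 0.47 (0.31 to 0.63). The number of lower members was 1 (3) of 11 interneuron markers, 1 (2) of the protocadherin beta genes, 2 (2) of 13 developmental transcription factors, 0 (1) of 17 potassium channel genes, 0 (1) of 8 thalamic and septal markers and 1 (1) of 13 neighbours of Mlh1. The excitatory neuron, alpha and gamma protocadherin, cholesterol, potassium channel and mitochondrial lists had adjusted camera p values of 0.0272, 0.0213, 4.28e-05, 0.0213 and 0.00135. With an estimated correlation these became adjusted p = 0.414, adjusted p = 0.463, adjusted p = 0.417, adjusted p = 0.404 and adjusted p = 0.463. In all 15 comparisons, 5 lists had 0 members past the threshold in edgeR adjusted over the list alone, namely the p53, oxidative phosphorylation, postsynaptic signalling, oligodendrocyte and Htt neighbour lists. Of these, 3 of 15 p53 target genes were higher and 1 lower at an unadjusted p under 0.05 in the wild-type tissue comparison, and the oligodendrocyte list had 15 of 16 markers negative there with a median of −0.17 (adjusted camera p = 0.0174, adjusted p = 0.575 with an estimated correlation). Choroid plexus markers had 11 of 12 negative there with a median of −0.94, 0 past the threshold adjusted over the list alone and an adjusted p of 0.156 in limma's camera.

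The tissue by Q140 KI interaction asks whether the knock-in effect differs between the tissue labels. Gjb6, a gap junction gene of astrocytes, was at −0.47 (−0.78 to −0.17) and was past the threshold adjusted over its list of 15 alone, and 14 of 15 astrocyte markers were negative with a median of −0.13 (adjusted camera p = 0.000237, adjusted p = 0.741 with an estimated correlation). Immediate early genes had 15 of 16 positive and a median of 0.67 (adjusted camera p = 2.91e-06, adjusted p = 0.741 with an estimated correlation). Microglia markers had 15 of 15 negative and a median of −0.48 (adjusted camera p = 1.04e-05, adjusted p = 0.741 with an estimated correlation). By the striatum label the upper Thy1 range held 6 wild-type and 3 Q140 KI libraries. By the cortex label it held 3 and 6 in the same order. The microglia shift in this interaction was not separated from that spread of Thy1. Over all 19170 genes edgeR called 0 with 520 at an unadjusted p under 0.05, and DESeq2 called 1, Ntrk1, the nerve growth factor receptor gene, named after its values were seen. Over the 15 comparisons and 28 lists, camera with a preset correlation called 111 of 420 tests and 1 of them held with an estimated correlation, the alpha and gamma protocadherins in cortex-labelled Mlh1+/- against wild type. That 1 call was adjusted within its comparison and not over the 420 tests.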

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

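The rule for outlying libraries was applied to every group, while the tests on the sex-linked and tissue marker genes, and those of Thy1 over groups and of Thy1 against Slc17a7, were chosen only after the result was seen. A library stood out by Dixon's rule in 6 of 72 groups of values, and chance alone gives about 1 in 20. The total count of the cortex-labelled Mlh1+/- male 3 was 57569077 where the others had 32913267 to 44381668, and that of the striatum-labelled wild-type male 4 was 55363048 where the others had 36690174 to 42742509. Mlh1 in the cortex-labelled Q140 KI male 5 was 9.36 CPM where the others had 7.19 to 8.17. Ppp1r1b in the striatum-labelled Q140 KI x Mlh1+/- female 3 was 57.0 CPM where the others had 79.0 to 93.0. Drd2 in the cortex-labelled Mlh1+/- male 4 was 16 CPM where the others had 1.23 to 4.52. Thy1 in the cortex-labelled Q140 KI x Mlh1+/- female 4 was 2106 CPM where the others had 700 to 885. All 6 were kept.

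The sex-linked genes and the tissue markers went against the labels. Libraries exchanged among the 64 may explain the sex part but not the tissue part, since 0 of 64 had more Ppp1r1b than Slc17a7. Genes listed out of order would not leave 63 of 64 libraries with exactly 1 of Xist and Ddx3y. Columns that hold other animals, or other tissue, than their labels say might explain both, and the 2 libraries of an animal showed the same sex in 14 of 32. The values do not tell which library belongs to which label, and no library was moved.

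Thy1 fell into 2 ranges within groups. Genotype and tissue as labelled did not divide the ranges, since 8 of 8 groups held both. If the columns hold other animals than their labels say, the true genotype or tissue could not be tested this way. A larger share of neurons could raise Thy1, but the log2 range of Slc17a7 was 0.286 of that of Thy1. A transgene under the Thy1 promoter that carries App sequence, which the labels do not mention, could raise both genes, and App followed Thy1 within the upper range (Spearman rho 0.557), as had been written down before that test. App followed Thy1 within the lower range too (rho 0.458, Pearson 0.665 where the upper range had 0.581, and 0.347 and 0.373 without the 2 farthest libraries), which leaves other causes open.

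Microglial genes were lower in striatum-labelled Mlh1+/- than in wild-type libraries, with a median of −1.06. The uneven spread of high-Thy1 libraries, 2 of 8 against 6 of 8, may account for most of this, since the median was −0.16 with log2 Thy1 CPM as a covariate. A difference in depth would not, since the median was −1.09 with the log2 total count as a covariate. Both of these predictions were written before the tests were run. An effect of the Mlh1+/- genotype could not be separated from the spread of Thy1, and Mlh1 itself was at −0.08.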

How the results depend on the processing

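Values here are log2 fold changes or counts of called genes under alternatives, with directions between labelled groups, and the cause of a change was not tested. A count stayed if it was equal or within a fixed fold of the main one, counts of 0 both times included. A gene value stayed if its sign and its call were unchanged, whatever its size. Stronger and weaker mean a call gained or lost. Chat in striatum-labelled Mlh1+/- against wild type thus stayed, at 1.75 and at 0.84 without Mlh1+/- female 3. The tallies therefore do not show that values kept their size. Of counts, 164 stayed and 18 moved under alternatives, and 406 stayed and 10 moved when a library was left out. Of gene values, 1316 stayed, 34 changed sign, 9 became stronger and 12 weaker under alternatives. When a library was left out, 3160 stayed, 38 changed sign, 5 became stronger and 29 weaker. Apart from Mlh1 and Htt and the genes named by the rule, the genes in this part were named after their values were seen.

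DESeq2 called 1, 3 and 0 genes by the striatum label in Q140 KI against wild type, Mlh1+/- against wild type and Q140 KI x Mlh1+/- against Q140 KI. It called 1 by the cortex label in Mlh1+/- against wild type, 2 in Q140 KI x Mlh1+/- against Q140 KI, 3 in the interaction, 1 in tissue by Q140 KI (Ntrk1) and 3 in sex by Q140 KI. Fits of 2 genotypes called 252 genes in striatum-labelled Mlh1+/- against wild type and 1 (Gm3608) in cortex-labelled Q140 KI x Mlh1+/- against Q140 KI. There Htt was −0.0011 in cortex-labelled Q140 KI against wild type. An adjusted p under 0.1 called 1 gene (Pcolce2) in cortex-labelled Q140 KI x Mlh1+/- against Q140 KI.

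Without a filter, 1 gene (Gm11815) was called in the cortex-labelled interaction and 548 between the tissue labels. Clec7a (adjusted p = 0.0591), Itgax (0.0562), Baiap3 (0.0617) and Bst2 (0.0550) then lost their calls, and Htt was −0.00070 in cortex-labelled Q140 KI against wild type. In limma on FPKM, Mlh1 was −0.00080 with 1 added and −0.00020 with 0.1 added in cortex-labelled Q140 KI x Mlh1+/- against wild type. RLE scaling called 904 genes between the tissue labels. At the male level that contrast called 410 (182 higher, 228 lower), and Clec7a (adjusted p = 0.147), Itgax (0.125), Lyz2 (0.0510), Cd52 (0.0785), Baiap3 (0.123), C1qa (0.0630) and Bst2 (0.110) lost their calls.

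With the replicate number as a block, Htt was 0.0019 in striatum-labelled Q140 KI x Mlh1+/- against Q140 KI. Rps4l was called in cortex-labelled Mlh1+/- against wild type with this block and with the plate column, and the other block counts within a tissue label were 0. With the animal as a block 856 genes were called between the tissue labels and 0 in tissue by Q140 KI. Baiap3 then lost its call at −1.55 (adjusted p = 0.0538) and Hba-a1 gained one at 2.702. The pairs of libraries by animal correlated at 0.018.

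In females alone, Mlh1 was −0.073 in striatum-labelled Q140 KI against wild type and Ttr −1.22 in Q140 KI x Mlh1+/- against Q140 KI. In males alone, Htt was −0.021 in the former and Mlh1 −0.14 in the latter of these comparisons, and Mlh1 0.017 and Htt −0.043 in cortex-labelled Q140 KI against wild type. In libraries whose sex-linked genes match their label, Mlh1 was 0.055 in striatum-labelled Mlh1+/- against wild type, Ttr −1.33 in Q140 KI x Mlh1+/- against Q140 KI and Htt −0.064 in Q140 KI x Mlh1+/- against wild type. By the cortex label there, Mlh1 was 0.070 in Q140 KI against wild type, Mlh1 −0.0085 and Ttr −1.28 in Q140 KI x Mlh1+/- against Q140 KI, and Htt 0.051 and Ttr −0.17 in Q140 KI x Mlh1+/- against Mlh1+/-. With log Xist in the fit, Mlh1 was −0.0084 in cortex-labelled Q140 KI x Mlh1+/- against wild type.

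With 5 surrogate variables, Htt by the striatum label was −0.014 in Q140 KI against wild type, −0.021 in Mlh1+/- against wild type, −0.018 in Q140 KI x Mlh1+/- against wild type, 0.0029 against Mlh1+/- and 0.017 in the interaction. Trem2 was −0.18 and Tyrobp −0.24 in Q140 KI x Mlh1+/- against Mlh1+/-, and Trem2 −0.048 in the interaction. By the cortex label Mlh1 was −0.017 in Q140 KI x Mlh1+/- against wild type and 0.0045 in the interaction, and Htt 0.015 in Q140 KI x Mlh1+/- against Mlh1+/-. In cortex-labelled Q140 KI x Mlh1+/- against Q140 KI 3 genes were called (Pcolce2 with adjusted p = 0.0221, Gm10704 and Gm12586). Without the 2 libraries that stood apart, Mlh1 by the striatum label was −0.042 in Q140 KI x Mlh1+/- against Q140 KI and −0.0076 against wild type, where Htt was −0.010.

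With each library left out in turn, the count was 0 to 1 in cortex-labelled Mlh1+/- against wild type (Rps4l without wild-type F1 or M1) and 0 to 1 in the interaction (Nr1d2 without wild-type M1). It was 0 to 2 in Q140 KI x Mlh1+/- against Q140 KI, with Pcolce2 and Gm3608 without Mlh1+/- M3, and Pcolce2 without Q140 KI x Mlh1+/- F2, Q140 KI F1 or Q140 KI M3. Between the tissue labels it was 530 to 992. By the cortex label Htt ranged from −0.032 to 0.029 and Mlh1 from −0.065 to 0.0074 in Q140 KI against wild type, Htt from −0.043 to 0.019 in Q140 KI x Mlh1+/- against Mlh1+/-, Mlh1 from −0.015 to 0.038 against wild type, and Htt from −0.046 to 0.017 in the interaction. By the striatum label Htt ranged from −0.012 to 0.051 and Mlh1 from −0.025 to 0.077 in Q140 KI against wild type, and Htt from −0.048 to 0.0025 in Q140 KI x Mlh1+/- against Mlh1+/-. Htt ranged from −0.016 to 0.035 in Q140 KI x Mlh1+/- against wild type and from −0.034 to 0.027 against Q140 KI, where Ttr ranged from −1.03 to 5.59.

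The list tests with an estimated correlation called 1 of 420 and fry 9, where the preset correlation called 111. The cortex-label score difference between Q140 KI x Mlh1+/- and Q140 KI was −0.094 with the sets of 4 split by first and last numbers in place of odd and even ones (exact permutation p = 0.390).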

Other observations

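The relations in this part were chosen only after the Thy1 ranges were seen. Within the 31 libraries of high Thy1, the level of Thy1 rose with that of App, the amyloid precursor protein gene, Psen1, the presenilin 1 gene, and the mean of the microglia markers. For App the Pearson correlation was 0.581 (permutation p = 0.00048, adjusted p = 0.00072) and the Spearman correlation 0.557 (permutation p = 0.00157, adjusted p = 0.00314). For Psen1 they were 0.715 (adjusted permutation p = 6e-05) and 0.710 (adjusted permutation p = 0.00012), and for microglia markers 0.686 (adjusted permutation p = 6e-05) and 0.647 (adjusted permutation p = 0.00042). Without the 2 libraries farthest from the centre they were 0.589 for App, 0.696 for Psen1 and 0.583 for microglia markers. Within the 33 libraries of low Thy1 the Pearson correlation for App was 0.665 (adjusted permutation p = 0.00022) and the Spearman correlation 0.458 (adjusted permutation p = 0.0119), and they were 0.373 and 0.347 without the 2 farthest libraries. For Psen1 they were 0.463 (adjusted permutation p = 0.00815) and 0.254 (adjusted permutation p = 0.156), and for microglia markers 0.365 (adjusted permutation p = 0.0406) and 0.258 (adjusted permutation p = 0.156). Without the 2 farthest libraries the Pearson values were 0.286 and 0.0438, so that these last 2 relations rest on those libraries. These were 6 relations with 100000 permutations each, over groups and tissue labels together. No value was computed within plate columns or with the means of columns or groups removed.

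The cortex-labelled Mlh1+/- library of female 1 differed from the others in more than the absence of Xist and Ddx3y. Neurod6, a transcription factor gene of excitatory neurons, was at 200 CPM there while the median of cortex-labelled libraries was 61.3 CPM. Tbr1 was at 59.7 CPM against a median of 193 CPM and Satb2 at 21.5 CPM against 97.5 CPM. Rpl3, a ribosomal protein gene, fell into 2 sets among cortex-labelled libraries, from 2.38 to 3.83 CPM and from 17.9 to 43.0 CPM, as was seen after the values were examined. The lower set held 5 of 8 wild-type, 0 of 8 Mlh1+/-, 7 of 8 Q140 KI and 3 of 8 Q140 KI x Mlh1+/- libraries. Rpl3 ranged from 29.7 to 48.7 CPM with a median of 40.5 CPM among striatum-labelled ones.

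Other medians of marker genes by label were 10.5 and 13.9 CPM for Drd1 and 2.27 and 9.75 CPM for Adora2a, striatum label first. With log2 Thy1 CPM as a covariate the median of the microglia markers was 0.242 in place of 1.18 in striatum-labelled Q140 KI x Mlh1+/- against Mlh1+/-, and 0.289 in place of 1.58 in the interaction. Libraries numbered alike within a sex were not more alike, with mean correlations of 0.014 among striatum-labelled (14 of 45 above 0.1) and −0.021 among cortex-labelled libraries (12 of 45).

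Each comparison was run on 40 labellings of the same libraries within a tissue label and 25 over all 64, of which 1 was the real one and the other 39 and 24 dealt the labels out anew. For a comparison with 0 called genes every labelling, 40 of 40 or 25 of 25, has at least 0 by definition, so that the repeat tests nothing there and no conclusion is drawn from it. The highest other count under the striatum label was 0 for Q140 KI against wild type, 38 for Mlh1+/- against wild type, and 1, 2061 and 1 for Q140 KI x Mlh1+/- against Q140 KI, wild type and Mlh1+/-. It was 350 for the interaction and 1 for sex by Q140 KI. Under the cortex label it was 47, 0, 1, 1, 3 and 92 for the first 6 of these in the same order, and 1 for the tissue by Q140 KI interaction. Labellings were also counted that reached the real number of genes at an unadjusted p under 0.05, the real one included. For these 6 comparisons they were 27, 9, 17, 13, 4 and 3 of 40 by the striatum label. By the cortex label they were 31, 9, 13, 36, 6 and 3 of 40. Labellings with 2061, 350 or 92 called genes show that labels dealt out anew can give many calls in these libraries. What set those labellings apart was not examined. For the wild-type tissue labels 1 of 25 labellings, the real one, reached 896 genes and the highest other had 7. With 24 others this shows only that the real one ranked first, which does not exclude chance. Labels were swapped within labelled animals, and plate columns change with the tissue label.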
